A study of Homo sapiens with 8 samples.

How the data were processed

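The deposited values number 1 per probe set and array on 8 arrays with 54675 probe sets, 62 of which are control probe sets. Per the labels, 200 ng of total RNA were converted to biotin-labelled cRNA with a 3' IVT kit and hybridized to the arrays. The deposited values are signal intensity on a linear scale, made by the authors with MAS5 in Affymetrix Expression Console according to the submitters' processing notes, which give no version. Each array had been scaled so that its mean, with the lowest and highest 2% of values left out, was the same, and no other normalization between arrays was found. Nothing in the notes names a genome build, and none is needed for probe set signals.

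Probe sets were named from the platform's probe annotation. Of them, 41097 name a single gene, 1801 several and 11777 none. Through their Entrez identifiers, 41043 symbols were updated to current ones, and 54 were kept as given. A reference gene table of the assembly GRCh38.p14 was used for which genes neighbour each other. Probe sets that name several genes or none were left out of the gene tests.

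Signals were taken as deposited, 10 was added (the 20th percentile of all signals, rounded), and log2 was taken. Probe sets were kept where the signal exceeded the median of all values, 60.0, on at least 2 arrays, which left 32646, of which 26725 name a single gene. Each gene was represented by its probe set with the highest mean log2 signal over all arrays, giving 14162 genes. All 8 arrays were fitted in 1 linear model of the 4 groups with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3, with the data.table package (version 1.17.8). The fit had 4 residual degrees of freedom and 5.37 prior degrees of freedom. Contrasts were CEP701 minus DMSO, PRMT5 shRNA minus scramble, the difference of these effects, and scramble minus DMSO. Adjusted p-values are Benjamini-Hochberg values within a contrast, with a threshold of 0.05; fold changes include the added 10, and means and SDs are of the signals as deposited.

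The 26 gene lists cover signalling targets, cell cycle, metabolism, stress, PRMT5 partners and targets, and markers of blood and other cell types. The lists, the contrasts, the model, the filter, most alternatives and the rule for named genes were chosen before the data were examined. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the residuals. The estimate was below 0.01 for some lists, such as ERK (-0.0054), NF-kB (-0.014) and immediate early genes (-0.040). For others it was far above 0.01, such as megakaryocyte (0.825), MYC (0.735), G1/S (0.688), G2/M (0.647), heat shock (0.503) and hypoxia genes (0.357). At the preset value the genes of those lists count as nearly independent. Their adjusted p at that value is too small if the estimate holds. Where the ERK, NF-kB and immediate early lists lost a call with the estimate, a larger correlation was not the cause. The calculation with the estimate thus differs from the preset one in more than the size of the correlation. A call lost with it cannot be credited to correlated genes alone. Counts adjusted over the list alone use only the list's own genes in the adjustment. The named genes were PRMT5, the 10 largest rises and 10 largest falls among genes that passed with both treated arrays beyond both control arrays, up to 4 members of each shifted list and up to 2 of each other list by lowest unadjusted p, and the 5 largest in each direction of the difference. Where fewer than 10 passed in a direction, genes of lowest unadjusted p were added up to 5 and given as not passing.

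Correlations between the effects were computed across genes as Pearson's r and Spearman's rho. Overlaps of called genes were set against the number expected if calls were independent, with Fisher's exact test, which treats genes as independent. The shRNA arrays share a suffix in their titles by replicate, and the deviations of the paired arrays from their group means correlated across genes (r = 0.323), so values with a replicate block are given beside the shRNA results. The drug arrays share only a replicate number, and their deviations did not correlate (r = -0.0115).

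The calculation was tested on simulated data with 14162 genes, the fitted variances and known changes, in 10 simulations. A true 2-fold change was recovered for 41.1% of genes with CEP701 and 44.3% with PRMT5 shRNA, a 4-fold change for 80.8% and 77.5%, and 7.52% and 6.65% of calls were false. A shifted list had an unadjusted camera p under 0.05 in 10 of 10 simulations and an unshifted list in 0 of 10. That held with the preset and with the estimated correlation. Lists in the results were called by adjusted p, which is a stricter rule. Genes were simulated independently, so these rates say nothing about correlated lists. Each gene was given the same spread on all arrays of both arms, with no effect of a replicate pair. The similar rates of the 2 comparisons were thus built in, and rates under each arm's own spread were not tested.

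Alternatives were quantile normalization, median scaling, pseudocounts of 1 and 40, no filter and a stricter filter (a signal above 247), every probe set by itself, the mean of a gene's probe sets, and leaving out probe sets ending in _x_at. Others were eBayes without a trend or with robust hyperparameters, fitting only the 4 arrays of a comparison, a replicate block in both arms, a 2-fold minimum, the estimated correlation, and leaving out each array in turn. After the data had been seen, scaling to the 12 poly-A control probe sets and a replicate block in the shRNA arrays alone were added. No sample was left out of the main results. With groups of 2, no test for outlying arrays was made and no other splits of the samples were counted.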

Results

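Gene expression was measured on 8 Affymetrix arrays carrying 54675 probe sets, in cells that the labels name HEL, a human erythroleukaemia line with an activating JAK2 mutation. In the drug arm, 2 arrays came from cells given CEP701 and 2 from cells given its vehicle, DMSO. CEP701 is lestaurtinib, an inhibitor of the JAK2 and FLT3 kinases, and was added at 0.5 µM for 16 h. In the shRNA arm, 2 arrays came from cells with a stable lentiviral shRNA against PRMT5, an enzyme that methylates arginines of histones, Sm proteins and other targets, and 2 from cells with a scramble control. The series set out to compare the profile of the drug-treated cells with that of the PRMT5 knockdown cells. Pearson's r between arrays, across 14162 genes on the log2 scale, was 0.964 to 0.978 within a group, 0.954 to 0.972 between groups of an arm and 0.804 to 0.845 between arms. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 2 arrays per group, the number of arrays limits the precision of every value.

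PRMT5 was lower on the PRMT5 shRNA arrays than on the scramble arrays at each of its 3 probe sets, at 35.2%, 41.7% and 45.8% of the scramble mean. The probe set with the highest signal averaged 489 ± 247 on the PRMT5 shRNA arrays and 1389 ± 572 on the scramble arrays (SD, n = 2). Its log2 difference was -1.52 ± 0.35 (SE), and -1.42 and -1.61 within the replicate pairs, which carry the same title suffix. The difference did not pass the test over all genes (adjusted p = 0.217). With the replicate block, which removes the spread between the pairs, it passed (adjusted p = 1.56e-04), and over all alternatives the adjusted p ranged from 8.91e-05 to 0.910. On the CEP701 arrays PRMT5 averaged 2887 ± 193 against 3320 ± 140 with DMSO, and the log2 difference of -0.20 did not pass the test (adjusted p = 0.766).

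**Figure D1:**
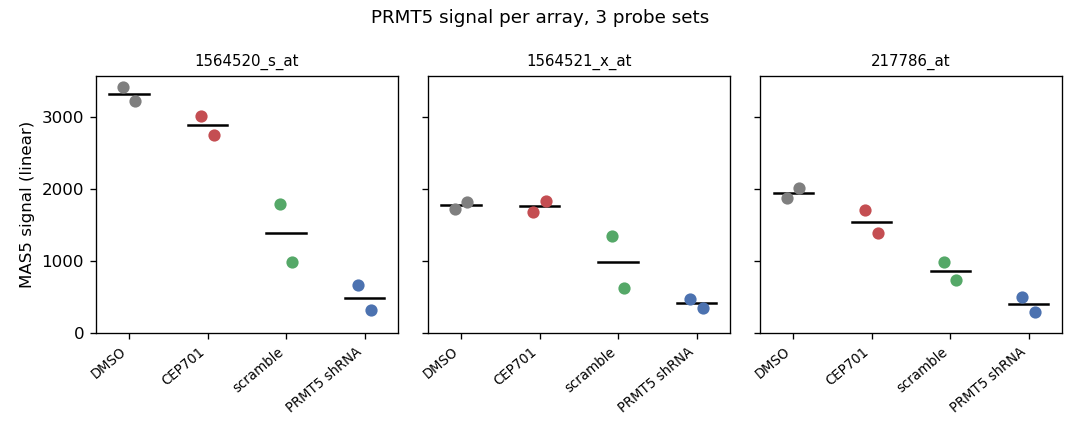
MAS5 signal of PRMT5 on a linear axis in the 4 groups, with a panel for each of the 3 probe sets. Points are single arrays and bars are means of 2, and at every probe set both PRMT5 shRNA arrays lie below both scramble arrays, and the DMSO and scramble groups differ in level.

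The comparison of CEP701 with DMSO asked which transcripts the kinase inhibitor changed within 16 h. Several transcripts that report on JAK-STAT and ERK signalling fell. DUSP6, a phosphatase that dampens ERK and is itself induced by ERK signalling, fell 12.6-fold, from 1721 ± 202 to 128 ± 7.68 (SD, n = 2; adjusted p = 5.67e-04). PIM1, a survival kinase induced by STAT5, fell 4.71-fold (adjusted p = 7.96e-04), and SOCS3, a feedback inhibitor of JAK kinases, fell 5.72-fold (adjusted p = 9.46e-03). ID1, a transcriptional inhibitor, fell 7.10-fold (adjusted p = 2.31e-03).

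Of the 16 measured JAK-STAT target and feedback genes, 5 fell and 1 rose (median log2 change -0.68; adjusted over the list alone, 9 fell and 1 rose). The list was shifted down by camera (adjusted p = 5.26e-08), and had adjusted p = 0.134 with an estimated correlation. Besides PIM1, ID1 and SOCS3, PIM2 fell (log2 change -2.27), as did GFI1B, a repressor needed in erythroid and megakaryocyte cells (-1.24). Of 15 ERK feedback and target genes, 4 fell and 1 rose (median -1.04; adjusted over the list alone, 8 fell and 1 rose; adjusted p = 2.13e-05, and adjusted p = 0.123 with an estimated correlation). ETV5, a transcription factor downstream of ERK, fell (-2.73), as did DUSP5 (-1.27), while SPRY1, an inhibitor of receptor signalling, rose (1.82).

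The lists of DNA replication and ribosome synthesis genes were shifted down. Of 41 G1/S and DNA replication genes, 10 fell and none rose (median -0.75; adjusted over the list alone, 24 fell), including CHAF1A, a histone chaperone, at -1.10 and RRM2, a subunit of ribonucleotide reductase, at -0.76. That list had adjusted p = 1.93e-16, and adjusted p = 0.478 with an estimated correlation. Of 37 MYC target and ribosome biogenesis genes, 2 fell (median -0.56; adjusted over the list alone, 9 fell), namely POLR1G, a subunit of RNA polymerase I, at -1.83 and DDX21, a nucleolar helicase, at -1.12 (list adjusted p = 9.05e-11, and adjusted p = 0.577 with an estimated correlation). Of 36 G2/M and mitosis genes none passed over all genes or adjusted over the list alone, and the list's small shift (median -0.16) had adjusted p = 0.0344, and adjusted p = 0.750 with an estimated correlation. That call was lost under quantile normalization, with the stricter filter, without the _x_at probe sets, without CEP701 replicate 1 and without DMSO replicate 2. Without those arrays the median relative to all genes was -0.30 and -0.24.

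The sterol, ATF4 and heat shock lists were shifted down too. Of 18 sterol synthesis genes, 8 fell (median -0.60; adjusted over the list alone, 12 fell), among them HMGCS1, which makes the precursor of mevalonate, at -1.02, and MSMO1 at -1.14 (list adjusted p = 9.05e-11, and adjusted p = 0.135 with an estimated correlation). Of 28 ATF4 and unfolded protein response genes, 10 fell (median -0.63; adjusted over the list alone, 15 fell and 1 rose). Among them were PSAT1, of serine synthesis, at -2.26, ASNS, which makes asparagine, at -1.71, and HSPA5, the main chaperone of the endoplasmic reticulum, at -1.13 (list adjusted p = 9.05e-11, and adjusted p = 0.123 with an estimated correlation). Of 12 heat shock genes, 5 fell (median -0.70; adjusted over the list alone, 10 fell), including the chaperones HSPH1 at -1.18 and DNAJA1 at -0.98 (list adjusted p = 1.67e-07, and adjusted p = 0.447 with an estimated correlation).

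The list of genes that FOXO factors induce, or that PI3K signalling represses, was shifted up. Of 22 measured, 4 rose and none fell (median 0.74; adjusted over the list alone, 9 rose): YPEL3 by 2.54, SESN3, an inhibitor of mTORC1, by 1.76, YPEL5 by 1.52 and TXNIP, an inhibitor of glucose uptake, by 1.05 (list adjusted p = 1.90e-05, and adjusted p = 0.577 with an estimated correlation). Of 28 interferon-stimulated genes, 6 rose (median 0.38; adjusted over the list alone, 11 rose and 1 fell), including IFIT2 at 2.13 and IFIH1, a sensor of double-stranded RNA, at 1.36. That list had adjusted p = 6.84e-03, and adjusted p = 0.577 with an estimated correlation. Scaling to the poly-A controls, which moves all genes alike, put its median at -0.13 but left it 0.28 above that of all genes, as without this scaling, and still called. The call was lost without DMSO replicate 1, with a median relative to all genes of 0.26.

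The splicing and methylation lists were shifted down as well. Of 22 Sm protein and SMN complex genes, SNRNP70 and LSM10 fell, at -0.95 and -0.83 (list median -0.23; adjusted over the list alone, 2 fell; adjusted p = 2.96e-04, and adjusted p = 0.577 with an estimated correlation). Of 13 arginine methyltransferases and PRMT5 partners, COPRS, which links PRMT5 to histones, fell by 0.94 (list median -0.42; adjusted over the list alone, 1 fell; adjusted p = 5.59e-04, and adjusted p = 0.577 with an estimated correlation).

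Among genes mostly outside these lists, THBS1, a secreted adhesive protein of platelets, rose 18.1-fold to 16695 ± 604 (SD, n = 2; adjusted p = 1.76e-03). DUOX2, an oxidase that makes hydrogen peroxide, rose from a signal near background, 6.43 ± 6.34, to 533 ± 45.7 (adjusted p = 2.34e-03). PAPPA, a protease that cleaves IGF-binding proteins, rose from 14.7 ± 13.4 to 740 ± 86.0 (adjusted p = 2.31e-03). For both, the DMSO signal lay below the filter's minimum, so the added 10 sets the size of the fold. CD24, a surface glycoprotein, fell 18.0-fold (adjusted p = 1.44e-03). MME, CCDC13, GBP4, TP53INP1, DPEP2, S1PR1 and RDH10 rose by 3.04 to 3.62 on the log2 scale, and PTPRR, PLEKHO1, PLEK2, GJB2 and MARCKSL1 fell, with log2 changes of -3.12 to -2.40.

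In the 14 lists that camera did not call, single members still passed. KIT, the receptor of stem cell factor, rose by 1.95, and 3 of 31 erythroid genes rose and 1 fell, with FECH and ALAD, enzymes of haem synthesis, at 1.20 and 1.32 (list adjusted p = 0.237). Of 29 hypoxia and glycolysis genes, 3 rose and 2 fell (adjusted p = 0.0987), with VEGFA, an angiogenic factor, at -1.55 and SLC2A1, a glucose transporter, at 1.03. Of 16 BCL2 family genes, the anti-apoptotic BCL2A1 rose by 1.13 and the pro-apoptotic PMAIP1 fell by 1.28 (adjusted p = 0.107), and of 21 p53 targets 2 rose and 1 fell, with TP53INP1 at 3.19 and AEN at -1.99 (adjusted p = 0.729). CTSB was the riser among 22 autophagy and lysosome genes (0.92; list adjusted p = 0.0684), and JUN among 14 immediate early genes (1.04; adjusted p = 0.729). Of 17 NF-kB targets, CXCL8 and TNFAIP3 were the 2 that rose and 1 other fell (adjusted p = 0.729). Of 27 megakaryocyte genes, THBS1 and CD36 were the 2 that rose (adjusted p = 0.945), and of 19 monocyte and granulocyte markers, CEBPA fell by 0.89 (adjusted p = 0.928). Besides KIT, none of 12 stem and progenitor genes passed (adjusted p = 0.443), and neither did any lymphocyte marker (adjusted p = 0.364), epithelial or fibroblast marker (adjusted p = 0.608), cyclin-dependent kinase inhibitor or pocket protein (adjusted p = 0.369), or gene described as PRMT5-repressed (adjusted p = 0.903). Adjusted over the list alone, the numbers higher and lower were 4 and 1 for erythroid, 4 and 5 for hypoxia, 1 and 2 for BCL2 family, 4 and 3 for p53, 3 and 1 for NF-kB, 3 and 0 for immediate early and 2 and 0 for megakaryocyte genes. They were 1 and 0 for the autophagy, stem and progenitor, and kinase inhibitor lists, 0 and 1 for monocyte and granulocyte markers, and 0 for the others.

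In all, limma called 819 of 14162 genes, 530 higher and 289 lower with CEP701, of which 326 and 129 changed at least 2-fold, and camera shifted 12 of 26 lists, 2 up and 10 down. No list kept its call with an estimated correlation, where the lowest adjusted p was 0.123. For the ERK list the estimate, -0.0054, was below the preset 0.01, so a larger correlation did not end that call. The count depended on single arrays: it was 6 without CEP701 replicate 1, 18 without CEP701 replicate 2, 50 without DMSO replicate 1, 23 without DMSO replicate 2 and 1233 without PRMT5 shRNA replicate 2, and of 68 named calls 5, 12, 19 and 13 were kept without the CEP701 and DMSO arrays in that order. The balance of rises and falls depended on the scaling, with 315 higher and 559 lower under median scaling and 74 higher and 942 lower under scaling to the poly-A controls, which moved the median of all genes from 0.10 to -0.41. The 5' to 3' signal ratio of the actin control probe sets, a measure of RNA quality, was 0.116 and 0.161 on the CEP701 arrays and 0.199 and 0.198 on the DMSO arrays. The same ratio for GAPDH did not separate the groups, at 0.787 and 0.856 with CEP701 and 0.882 and 0.809 with DMSO.

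**Figure D2:**
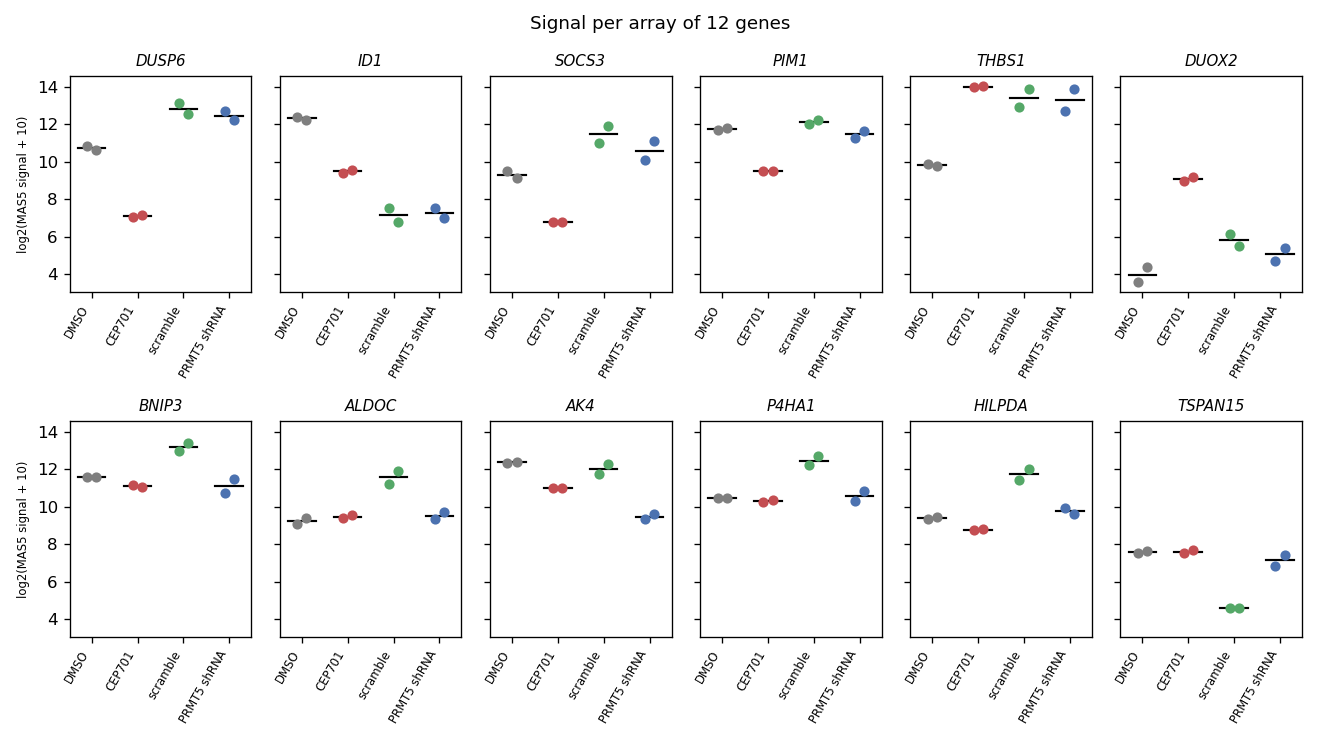
Log2 signal (MAS5 signal plus 10) per array of 12 genes in the 4 groups, where points are single arrays and bars are means of 2. DUSP6, ID1, SOCS3 and PIM1 were lower and THBS1 and DUOX2 higher on both CEP701 arrays than on both DMSO arrays, and BNIP3, ALDOC, AK4, P4HA1 and HILPDA were lower on both PRMT5 shRNA arrays than on both scramble arrays.

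The comparison of PRMT5 shRNA with scramble asked which transcripts differ after knockdown of the methyltransferase. Several genes that low oxygen induces fell. AK4, a mitochondrial adenylate kinase induced in hypoxia, fell 5.90-fold, from 4275 ± 1131 to 707 ± 103 (SD, n = 2; adjusted p = 3.29e-03). BNIP3, which directs mitochondria to autophagy, fell 4.32-fold (adjusted p = 0.0136), ALDOC, a glycolytic aldolase, 4.14-fold (adjusted p = 0.0213), and P4HA1, a collagen prolyl hydroxylase, 3.71-fold (adjusted p = 0.0136).

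Of 29 hypoxia and glycolysis genes measured, 3 fell over all genes tested, namely BNIP3, ALDOC and P4HA1, and 27 fell when adjusted over the list alone (median log2 change -1.06). All 29 were lower in both replicate pairs, with medians of -1.09 and -1.01. The list was shifted down by camera (adjusted p = 3.81e-42), and had adjusted p = 0.0879 with an estimated correlation. With the replicate block, which pairs the arrays by the shared suffix, 24 of the 29 fell. PFKFB3, which drives glycolysis, was at -1.06 (adjusted p = 0.0704, with 3.63e-03 to 0.529 over the alternatives). It passed in 4 of 23 alternatives, namely both blocks, quantile normalization and the mean of probe sets.

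Camera also shifted the NF-kB, immediate early, ERK and JAK-STAT lists down. Of 17 NF-kB target genes, IL1B, an inflammatory cytokine, fell by 1.66 (adjusted p = 0.0411; list median -0.69; adjusted over the list alone, 4 fell). That list had adjusted p = 1.08e-09, and adjusted p = 0.0570 with an estimated correlation. IL1B itself passed in 13 of 23 alternatives. CCL4 stood at -1.77, CXCL8 at -1.50 and TNFAIP3 at -0.79, and each passed with the replicate block but not without it. No gene passed over all genes or adjusted over the list alone among 14 immediate early genes (median -0.43; list adjusted p = 3.19e-04, and adjusted p = 0.0879 with an estimated correlation) or 15 ERK targets (median -0.39; list adjusted p = 3.16e-04, and adjusted p = 0.0879 with an estimated correlation). Of 16 JAK-STAT targets none passed over all genes and 2 were lower when adjusted over the list alone (median -0.18; list adjusted p = 3.19e-04, and adjusted p = 0.252 with an estimated correlation). PIM1, at -0.65, passed only with a block. Under the replicate block 4 NF-kB, 2 JAK-STAT, 1 immediate early and no ERK genes fell.

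In the opposite direction, 36 G2/M and mitosis genes had a median of 0.31 with no single gene passing, over all genes or adjusted over the list alone (list adjusted p = 3.39e-07, and adjusted p = 0.694 with an estimated correlation). CDC20, which triggers anaphase, was at 0.71. The same held for 28 interferon-stimulated genes (median 0.15; list adjusted p = 0.0137, and adjusted p = 0.694 with an estimated correlation) and 41 G1/S genes (median 0.16; list adjusted p = 0.0203, and adjusted p = 0.801 with an estimated correlation). It held for 37 MYC target genes (median 0.18; list adjusted p = 0.0209, and adjusted p = 0.801 with an estimated correlation) and 12 heat shock genes (median 0.21; list adjusted p = 0.0246, and adjusted p = 0.694 with an estimated correlation). Marker lists of other blood cells were shifted down, again with no gene passing over all genes or adjusted over the list alone: 27 megakaryocyte genes (median -0.29; list adjusted p = 1.97e-03, and adjusted p = 0.70 with an estimated correlation) and 19 monocyte and granulocyte markers (median -0.30; list adjusted p = 0.0209, and adjusted p = 0.694 with an estimated correlation). Under that block 2 G2/M, 2 MYC and 1 heat shock genes rose, 1 megakaryocyte and 2 monocyte and granulocyte genes fell, and no interferon or G1/S gene passed. These 7 shifts rested on single arrays. Without scramble replicate 2, the medians relative to all genes were 0.10 for G2/M, 0.10 for interferon, -0.11 for G1/S, -0.17 for MYC, 0.02 for heat shock, 0.33 for megakaryocyte and -0.20 for monocyte and granulocyte genes. Without PRMT5 shRNA replicate 1 they were 0.05 for G2/M, -0.15 for G1/S, -0.19 for MYC, 0.06 for heat shock, 0.22 for megakaryocyte and -0.05 for monocyte and granulocyte genes, and without PRMT5 shRNA replicate 2 the interferon median was -0.04.

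Among single genes outside the lists, RGS1, a regulator of G-protein signalling, fell 9.84-fold (adjusted p = 4.27e-03), and HAMP, the iron hormone hepcidin, 6.58-fold (adjusted p = 0.0103). FGF11, SPP1, HILPDA and SMIM24 fell, with log2 changes of -2.84, -2.50, -1.96 and -1.74. TSPAN15, a tetraspanin that partners the protease ADAM10, was the single gene that rose, from 14.3 ± 0.422 to 134 ± 40.3 (adjusted p = 0.0411). It passed in 10 of 22 alternatives. FUCA1, a lysosomal fucosidase, was at 1.46 (adjusted p = 0.0537, with 5.74e-04 to 0.529 over the alternatives) and passed in 7 of 23 alternatives, both blocks among them. ADAM9, TXNRD1 and TWF1, at 1.08, 0.65 and 0.82, passed only with a block.

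Without a block, no gene passed over all genes in the 14 lists that camera did not call. These were the erythroid (median 0.10; adjusted p = 0.195), stem and progenitor (-0.08; 0.330), lymphocyte (0.02; 0.456), epithelial and fibroblast (-0.28; 0.457), p53 (-0.09; 0.195), BCL2 (-0.03; 0.456), and kinase inhibitor lists (0.11; 0.935). The others were the PRMT5 partner (0.17; 0.456), Sm protein (0.05; 0.354), PRMT5-repressed (0.28; 0.134), sterol (0.02; 0.806), ATF4 (0.07; 0.935), autophagy (0.05; 0.0588) and FOXO lists (-0.24; 0.195), each given with its median and adjusted p. Adjusted over the list alone, 2 ATF4 genes, 1 BCL2 family gene and, in the PRMT5 partner list, PRMT5 itself were lower. In the fit with the replicate block, 2 erythroid genes and 1 ATF4 gene rose. In that fit 2 ATF4 genes and 1 gene each of the p53, BCL2, PRMT5 partner and FOXO lists fell, in the PRMT5 partner list PRMT5 itself. That block called 14 lists, the erythroid list (up; adjusted p = 0.0327) and the FOXO list (down; adjusted p = 0.0186) besides the 12. Over all alternatives their adjusted p ranged from 2.75e-07 to 0.908 and from 2.03e-04 to 0.800, and the erythroid list turned down without PRMT5 shRNA replicate 1 (median relative to all genes -0.19).

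In all, limma called 21 genes, 1 higher and 20 lower with PRMT5 shRNA, and 948 had an unadjusted p under 0.05. With the replicate block, 212 genes passed, 33 higher and 179 lower, among them the same 21. Camera shifted 12 lists, 5 up and 7 down, none of which kept the call with an estimated correlation (lowest adjusted p = 0.0570). The count of 21 genes was 4 without each of CEP701 replicate 1, CEP701 replicate 2, DMSO replicate 1 and DMSO replicate 2, 3 without scramble replicate 2 and 5 without PRMT5 shRNA replicate 1. RGS1 and AK4 kept their calls without each array. With only the 4 arrays of the shRNA arm, or with eBayes without a trend, no gene passed, RGS1 and AK4 included. In those limma fits 592 and 934 genes had an unadjusted p under 0.05. The actin 5' to 3' ratio was 0.187 and 0.335 on the PRMT5 shRNA arrays and 0.141 and 0.179 on the scramble arrays, and the GAPDH ratio ran the other way, at 0.729 and 0.778 against 0.846 and 0.883.

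**Figure D3:**
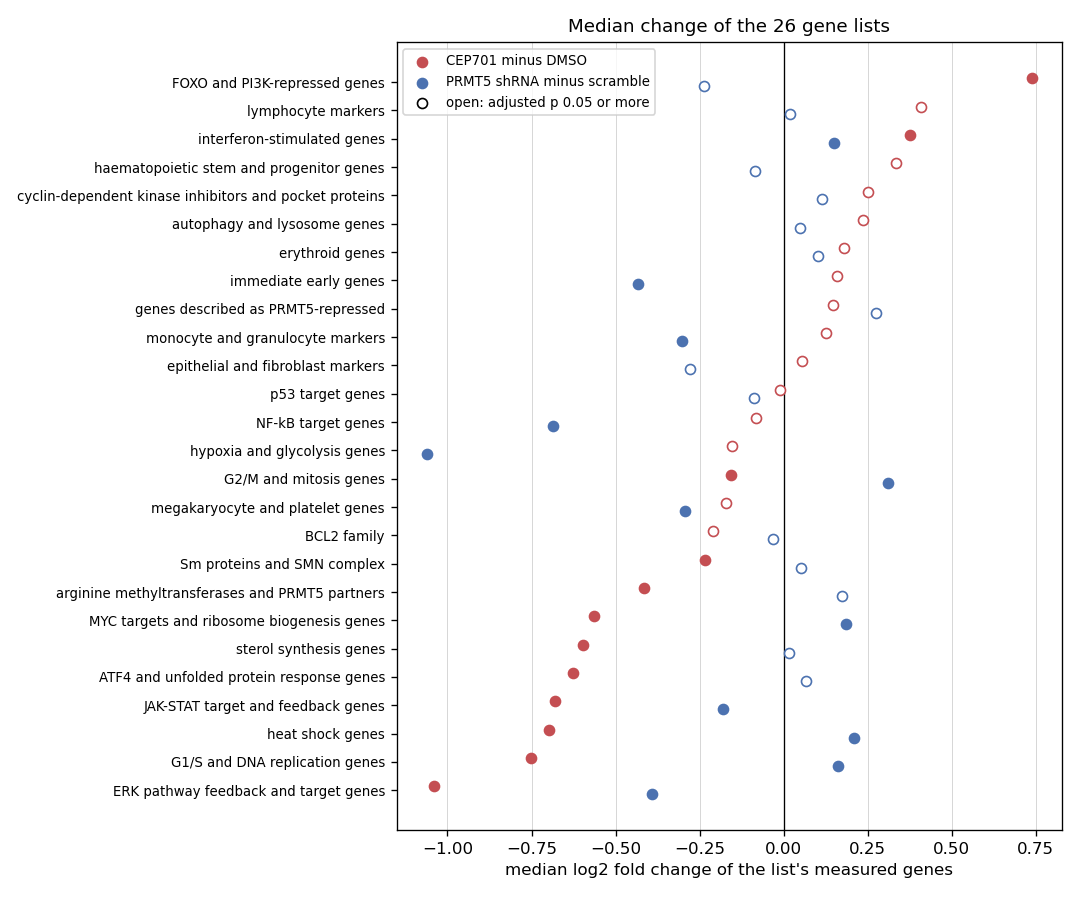
Median log2 fold change of the measured genes of each of 26 lists, with CEP701 minus DMSO in red and PRMT5 shRNA minus scramble in blue. Filled points had a camera adjusted p under 0.05. The hypoxia list lies at -1.06 with PRMT5 shRNA and the ERK list at -1.04 with CEP701, while G1/S, MYC and heat shock genes lie below 0 with CEP701. Their medians of 0.16, 0.18 and 0.21 with PRMT5 shRNA depend on single arrays.

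The test of the difference between the CEP701 and PRMT5 shRNA effects asked which genes responded unequally. The effects come from different arms, whose control groups differed at 6486 genes. Any difference between the arms' cells is therefore confounded with that between drug and knockdown. The same limit holds for the correlation of the effects and for the genes shared by them, given below. It passed for DUOX2 (5.87 higher on the log2 scale with CEP701; adjusted p = 0.0132), PAPPA (5.52), RGS1 (4.37; adjusted p = 6.98e-03), THBS1 (4.26) and GBP4 (3.97), and in the other direction for CD24 (-3.45), DUSP6 (-3.26; adjusted p = 6.98e-03), PLEKHO1 (-3.07), ID1 (-2.93) and TSPAN15 (-2.53). The sizes for DUOX2, PAPPA and TSPAN15 depend on the added 10, since their control signals were near background.

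Of 26 lists, 14 differed by camera, 4 up and 10 down. The hypoxia list differed upward by a median of 1.05, with 6 genes higher and 15 adjusted over the list alone (adjusted p = 2.68e-09, and adjusted p = 0.321 with an estimated correlation), and so did the FOXO (0.87), NF-kB (0.43) and immediate early lists (0.62). Those 3 had adjusted p = 5.72e-05, 8.14e-03 and 0.0364, and adjusted p = 0.468, 0.308 and 0.310 with an estimated correlation. They held 2, 3 and 1 genes higher, and 8, 5 and 1 adjusted over the list alone. The G1/S list differed downward by a median of -0.88 (no gene over all genes, 20 adjusted over the list alone; adjusted p = 6.27e-15, and adjusted p = 0.413 with an estimated correlation), and so did the heat shock (-0.98), MYC (-0.78), ATF4 (-0.71), PRMT5 partner (-0.68), sterol (-0.66), G2/M (-0.47), Sm protein (-0.32), ERK (-0.29) and JAK-STAT lists (-0.27). In that order these 9 lists had adjusted p = 8.85e-07, 4.14e-10, 2.34e-08, 3.20e-03, 1.81e-08, 1.52e-05, 1.14e-03, 0.0364 and 1.47e-03, and adjusted p = 0.321, 0.468, 0.308, 0.487, 0.308, 0.508, 0.508, 0.310 and 0.310 with an estimated correlation. Their genes lower numbered 2, 0, 4, 0, 1, 0, 1, 2 and 4, and 10, 0, 13, 1, 11, 0, 2, 2 and 6 adjusted over the list alone, with 1 ATF4 and 1 ERK gene higher, and 2 ATF4, 1 sterol, 1 ERK and 2 JAK-STAT genes higher adjusted over the list alone. No list kept its call with an estimated correlation. Under the replicate block 15 lists were called, the megakaryocyte list (up) besides the 14, and 30 G1/S, 24 MYC and 13 G2/M genes were lower in place of 0. The call was lost without 1 array for 5 lists: for ERK without DMSO replicate 1, scramble replicate 2 or PRMT5 shRNA replicate 2 (medians relative to all genes of -0.33, -0.29 and -0.50), for immediate early genes without CEP701 replicate 1, DMSO replicate 2, scramble replicate 1 or PRMT5 shRNA replicate 2 (0.71, 0.33, 0.22 and 0.34), for NF-kB without scramble replicate 1 (0.29), and for PRMT5 partners and Sm proteins without PRMT5 shRNA replicate 1 (-0.54 and -0.23). Other alternatives that ended a call were median scaling, a pseudocount of 40, no filter and the stricter filter for ERK, leaving out the _x_at probe sets for immediate early genes, and every probe set by itself for PRMT5 partners. Scaling to the poly-A controls, which moves all genes alike, put the NF-kB median at -0.11 but left it 0.32 above that of all genes and still called.

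The difference passed for 203 genes, 157 higher and 46 lower, and 2814 had an unadjusted p under 0.05. The 203 became 0 without CEP701 replicate 1, CEP701 replicate 2, DMSO replicate 1 or DMSO replicate 2, with 2150, 1879, 2043 and 1912 genes at an unadjusted p under 0.05 in limma. They became 808 without scramble replicate 1, 66 without scramble replicate 2, 75 without PRMT5 shRNA replicate 1 and 514 without PRMT5 shRNA replicate 2. Under scaling to the poly-A controls 22 were higher and 24 lower. With the replicate block, which pairs the arrays within each arm, 2296 passed.

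Across the 14162 genes, which are not independent replicates, the CEP701 and PRMT5 shRNA effects had Pearson's r = -0.0721 and Spearman's rho = -0.133. Single pairs of arrays gave r of -0.0704 to -0.0228, and contrasts that mixed the replicates within groups gave -0.0534 to 0.0355. The sign turned without scramble replicate 2 (0.0482) and without PRMT5 shRNA replicate 1 (0.0468). Genes called in both comparisons were AK4, lower in both (0.408 genes expected if calls were independent), and ADD1, a membrane skeleton protein that rose with CEP701 and fell with PRMT5 shRNA (0.748 expected), both named after their values were seen. These 2 genes became 0 without each of the 4 drug-arm arrays, 5 without scramble replicate 1, 1 without scramble replicate 2 and 5 without PRMT5 shRNA replicate 2.

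The 2 control groups, scramble and DMSO, were compared to show how far the arms differed without drug or knockdown. All genes named here were chosen after their values were seen. Several genes of granulocytes and monocytes were high on the scramble arrays and near background with DMSO. S100A8, a calcium-binding protein of neutrophils and monocytes, averaged 23791 ± 2589 against 36.7 ± 10.2 (SD, n = 2; adjusted p = 3.65e-08), MPO, the peroxidase of neutrophil granules, 18634 ± 2770 against 31.1 ± 14.6, and CD14, a monocyte receptor, 1701 ± 70.9 against 2.88 ± 0.317. Of 19 monocyte and granulocyte markers, 16 were higher and 1 lower (median log2 difference 4.93; adjusted over the list alone, 16 higher and 1 lower; adjusted p = 1.99e-08, and adjusted p = 0.312 with an estimated correlation). TMPRSS3, a serine protease, and IGFBP5, which binds insulin-like growth factors, ran the other way, at 11.4 ± 14.2 and 45.2 ± 19.0 on the scramble arrays against 7660 ± 272 and 10486 ± 585 with DMSO.

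Single erythroid genes differed in both directions. The adult globins HBB and HBD were 18.2-fold and 34.7-fold higher on the scramble arrays, whereas the embryonic globin HBE1 was 14.6-fold lower, CA1, a carbonic anhydrase of red cells, 82.3-fold lower, and EPB42, of the red cell membrane, 11.3-fold lower. Of 31, 7 were higher and 8 lower, over all genes and adjusted over the list alone (adjusted p = 0.206). Of 27 megakaryocyte and platelet genes, 12 were higher and 4 lower (median 0.74; adjusted over the list alone, 12 and 4), with the platelet chemokines PF4 and PPBP at 4.20 and 6.03. The call (adjusted p = 0.0304, and adjusted p = 0.693 with an estimated correlation) was lost without scramble replicate 2, with a median relative to all genes of 0.07. It was lost too with the replicate block, where 11 genes higher and 9 lower by the unblocked difference passed. Between arms that fit compares the fitted levels of replicate 1, which is a different contrast from that of the group means. The call was also lost with the block in the shRNA arrays alone, with the stricter filter, with the mean of probe sets and without the _x_at probe sets. Of 28 interferon-stimulated genes, 26 were higher (median 2.97; adjusted over the list alone, 26; adjusted p = 3.85e-14, and adjusted p = 0.183 with an estimated correlation). Of 37 MYC and ribosome biogenesis genes, 30 were lower (median -1.33; adjusted over the list alone, 33; adjusted p = 2.71e-10, and adjusted p = 0.452 with an estimated correlation). Of 29 hypoxia genes, 20 were higher (median 1.16; adjusted over the list alone, 21 higher and 1 lower; adjusted p = 3.11e-05, and adjusted p = 0.452 with an estimated correlation).

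Lists also shifted up were NF-kB (median 2.45), immediate early (2.26), FOXO (2.22), kinase inhibitor (1.24), ERK (1.11), sterol (0.85), p53 (0.84) and autophagy (0.62). In that order they had adjusted p = 1.30e-07, 3.35e-05, 2.44e-05, 0.0304, 6.24e-03, 4.84e-04, 3.56e-03 and 0.0105, and adjusted p = 0.0981, 0.127, 0.452, 0.367, 0.183, 0.367, 0.183 and 0.452 with an estimated correlation. Of their genes 14, 11, 15, 5, 8, 11, 13 and 13 were higher, and 15, 11, 15, 5, 8, 12, 13 and 13 adjusted over the list alone, with 4 p53 and 2 autophagy genes lower either way. Lists shifted down were heat shock (-0.99), G2/M (-0.77), G1/S (-0.72), Sm protein (-0.68) and PRMT5 partner (-0.64). These had adjusted p = 3.95e-03, 1.84e-05, 1.20e-06, 2.50e-05 and 6.41e-03, and each adjusted p = 0.452 with an estimated correlation. Of their genes 9, 19, 23, 15 and 7 were lower, and 9, 19, 25, 15 and 7 adjusted over the list alone, with 1 G2/M and 1 G1/S gene higher either way.

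In all, 6486 of 14162 genes differed between the control groups, 3608 higher and 2878 lower with scramble, and 329 and 97 of these differed at least 16-fold. Camera shifted 18 lists, 12 up and 6 down, and none kept its call with an estimated correlation (lowest adjusted p = 0.0981). Fitted with the replicate block, 16 were called, the megakaryocyte and kinase inhibitor lists losing their calls. The kinase inhibitor list also lost it with the block in the shRNA arrays alone, with the stricter filter and with the mean of probe sets. A block pairs arrays within an arm, so between arms these fits compare the fitted level of replicate 1 in each blocked arm. The median of all genes became 0.0987 with the replicate block and 0.0909 with the block in the shRNA arrays alone. Calls lost with a block thus belong to a different contrast from that of the group means. Under scaling to the poly-A controls 1958 genes were higher and 3663 lower, and under median scaling 2453 and 4403, with the median of all genes moved from 0.11 to -0.29 and -0.24. Vector, culture and any difference between the cells themselves are confounded with the arm, so each effect of drug or shRNA stands against its own control. A comparison of the effects with each other is not freed of these differences by that.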

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

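The tests in this part were chosen only after the result was seen. The poly-A control transcripts, bacterial RNAs added to each sample before labelling and used in none of the comparisons, were higher on the CEP701 arrays than on the DMSO arrays by 0.51 on the log2 scale over 12 probe sets, a signal outside the gene measurement and above its level on the DMSO arrays, though not above that on every scramble array. A difference in hybridization or scaling over whole arrays would raise the hybridization controls, added after labelling, by as much, and it stays open although these rose by 0.15, since the excess of 0.36 was smaller than the 0.37 by which the scramble arrays differed from each other in the same measure. A lower amount of poly-A RNA per amount of total RNA after CEP701 may be the reason. The excess lay between 0.33 and 0.40 for every pair of a CEP701 and a DMSO array. In log2 level less the hybridization controls, however, the CEP701 arrays, at -3.54 and -3.60, lay within the shRNA arm's range of -3.72 to -3.35. The DMSO arrays, at -3.93 and -3.94, lay below all others. These values do not show whether the CEP701 arrays were high or the DMSO arrays low. A chance difference in the amount of control RNA added stays open as well, given that difference between the scramble arrays. With the arrays scaled to these controls, 942 genes were lower with CEP701 in place of 289.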

How the results depend on the processing

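Of the alternatives, scaling to the poly-A controls and a replicate block in the shRNA arrays alone were chosen after the data had been seen. Signal over background limits genes near the filter's minimum, where a fold change depends on the added 10. PRMT5 stayed at -1.52 on the log2 scale and passed with the replicate block and with the block in the shRNA arrays alone; without each array in turn it lay between -2.04 and -0.99. For CEP701 (819 genes) the counts were 455 with quantile normalization, 489 with no filter, 1254 with every probe set by itself, 537 with the mean of probe sets, 167 without a trend, 3208 with only 4 arrays, 3040 with the replicate block, 3155 with the block in the shRNA arrays alone, and 455 at 2-fold or more; without an array the range was 6 (CEP701 replicate 1) to 1233 (PRMT5 shRNA replicate 2). For PRMT5 shRNA (21 genes) they were 38 with every probe set, 212 with the replicate block, 247 with the block in the shRNA arrays alone, and 3 (without scramble replicate 2) to 27 without an array; limma gave 0 without a trend and 0 with only 4 arrays, where 934 and 592 genes had an unadjusted p under 0.05. For the difference (203 genes) they were 115 with quantile normalization, 132 with no filter, 117 with the mean of probe sets, 2296 with the replicate block, 2456 with the block in the shRNA arrays alone, 46 with poly-A scaling, and 0 (without each drug-arm array) to 808 (without scramble replicate 1); limma gave 0 without a trend, with 2430 genes at an unadjusted p under 0.05. For the controls (6486 genes) they were 12822 with every probe set and 4151 at 2-fold or more, and 4520 to 6795 without an array. A group left with 1 array is assumed to vary like the others. More probe sets and a 2-fold minimum change these counts by construction. Fewer arrays leave fewer degrees of freedom, but with only 4 arrays the CEP701 count rose to 3208 while the PRMT5 shRNA count fell to 0. Arrays of a group correlated at r = 0.977 and 0.978 in the drug arm and 0.965 and 0.964 in the shRNA arm. The fit of all arrays uses the same variance of a gene for both arms. With only 4 arrays the log2 changes stayed the same, with medians of all genes of 0.0988 for CEP701 and 0.00345 for PRMT5 shRNA. Only the estimated variance of a gene and its degrees of freedom changed, so both counts depend on sharing a variance between the arms. How much of this came from the arms' unequal spread was not tested, and neither was the cause for the other alternatives.

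The 12, 12 and 14 shifted lists became 0 in each comparison with an estimated correlation in camera, and the PRMT5 shRNA lists numbered 7 (without scramble replicate 2) to 16, against 11 to 13 with CEP701 and 13 to 14 for the difference. The correlation of effects was -0.0501 with a pseudocount of 1, -0.108 with 40, -0.0393 with no filter, -0.152 with the stricter filter, -0.133 as Spearman's rho, and -0.0228, -0.0472 and -0.0457 in single pairs; without an array it ran from -0.154 to 0.0482. Shared genes (2) numbered 4 with the stricter filter, 4 with every probe set, 0 without a trend, 0 with only 4 arrays, 94 with the replicate block, 113 with the block in the shRNA arrays alone, 1 at 2-fold or more and 0 to 5 without an array. With PRMT5 shRNA, 5 lists turned direction in camera without scramble replicate 2 or PRMT5 shRNA replicate 1, for monocyte and granulocyte genes with a median still below 0; their medians relative to all genes ranged, without an array, from -0.19 to 0.56 for erythroid, -0.85 to 0.33 for megakaryocyte, -0.58 to -0.055 for monocyte and granulocyte, -0.15 to 0.50 for G1/S and -0.19 to 0.53 for MYC genes, and the cause was not tested. Over all other alternatives and results, named genes stayed called or uncalled in 3625 cases, gained a call in 154, lost it in 476 and turned in 0. Lists stayed so in 2318, gained in 45, lost in 99 and turned in 8. A turn was counted only where the result was called with or without the alternative. An uncalled result that turned direction therefore counts among the 3625 or 2318.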

Other observations

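The first test below, on shared genes, the test of array batch, the test of neighbouring genes, the medians by array pairing and the gene examples were chosen only after results had been seen. CEP701 calls from the fit without a block (530 higher, 289 lower) were set against PRMT5 shRNA calls from the fit with the shRNA arrays blocked by pair (45 higher, 202 lower). Genes that rose with CEP701 overlapped with genes that fell with PRMT5 shRNA: 24 genes were shared where 7.56 would be expected if calls were independent (Fisher's exact test, adjusted p = 2.25e-06). The 24 include SLC2A1, the glucose transporter, NDRG1 and BNIP3L, both induced by hypoxia, TXNIP, which limits glucose uptake, and CXCL8, BCL2A1 and TNFAIP3, targets of NF-kB. In the reverse direction, 4 genes fell with CEP701 and rose with PRMT5 shRNA where 0.918 would be expected (adjusted p = 0.0263): the chaperones DNAJA1 and HSPH1, the mitotic kinase PBK, and TWF1. Genes lower in both numbered 7 against 4.12 expected (adjusted p = 0.266) and included PIM1, SOCS3, VEGFA, AK4 and PFKP, and 1 gene, CREG1, was higher in both against 1.68 expected. With both sets of calls from the fit without a block, 2 genes were shared in all. Of these, 1 rose with CEP701 and fell with PRMT5 shRNA against 0.748 expected (Fisher's exact test, adjusted p = 0.712). With both sets from the blocked fit 113 were shared. The set of genes that rose with CEP701 depends on the scaling, with 74 under scaling to the poly-A controls in place of 530. Genes that move together are not independent, so these p-values are too small by an unknown amount.

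The control arrays of the arms differed at 6486 genes although all 8 labels name the same line. Array batch or scaling would move the hybridization controls, and labelling the poly-A controls added before it, but their median absolute log2 differences were 0.114 and 0.41 while 426 genes differed at least 16-fold. A mixture in which the shRNA arrays hold 10 percent or more of the drug arm's cells would keep that arm's abundant transcripts above that share of their level, but 33 of 3036 abundant genes lay below it, among them IGFBP5, TMPRSS3 and CA1. Cells of 1 genome in another state remain possible: the largest shift of a chromosome's genes was 7.74 standard units between the controls and 5.52 in the other contrasts, and 0 of 1000 shuffled gene orders gave as high a window of neighbouring genes, which could come from co-regulated neighbours. A candidate explanation is that the arms hold cells of different origin, and the values given here do not settle it.

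Some neighbouring genes, chosen after their values were seen, were near background throughout the drug arm and well expressed in the shRNA arm. FOCAD ranged from 3.34 to 23.9 on the drug-arm arrays and from 547 to 846 on the shRNA-arm arrays, HACD4 from 1.63 to 17.5 against 3755 to 5826, KLHL9 from 4.86 to 65.0 against 2069 to 2683, and MTAP, a methionine salvage enzyme, from 1.54 to 15.8 against 374 to 604. TUSC1 and MLLT3 on either side were expressed in the drug arm, at means of 12281 and 4023 with DMSO against 1462 and 1393 with scramble. IFNA17 and CDKN2A, which lie among these genes, did not differ by the limma test (adjusted p = 0.245 and 0.0860), but their signals lay near the filter's minimum. IFNA17 ranged from 8.22 to 62.2 on the drug-arm arrays and from 7.26 to 105 on the shRNA-arm arrays. CDKN2A ranged from 6.57 to 81.8 against 78.5 to 147. They therefore do not show whether the low stretch is broken. The longest unbroken run of genes low on the drug arm alone lay elsewhere, with 5 genes that include RXRA and FCN1, and 1 of 1000 shuffled gene orders held a run as long. JAK2 and its neighbours AK3 and RCL1 were lower on the scramble arrays than on the DMSO arrays, with log2 differences of -1.67, -1.75 and -3.44. Nearby, CDC37L1, RLN2, RLN1, PLGRKT and RIC1 were lower too, at -0.82 to -2.74, while CD274 was at 0.40 (limma adjusted p = 0.138).

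Hypoxia and glycolysis genes were lower on the PRMT5 shRNA arrays, with all 29 lower in both pairs. A smaller share of a cell type that expresses them would lower that type's markers by as much. The hypoxia median lay below the lowest cell type median, -0.30 for monocyte and granulocyte markers, by a difference of -0.76 (standard error over genes 0.217). It lay below the medians of all 6 cell type lists in each of the 4 pairings of a PRMT5 shRNA and a scramble array. With PRMT5 shRNA replicate 1 and scramble replicate 2, however, the gap was -0.17, with -1.53 against -1.36 for megakaryocyte genes. That gap is smaller than the standard error, and it was -0.45 to -0.62 in the other pairings. The test covers only the cell types listed, so a change in the share of a cell type stays open. Chance variation in oxygen or cell density between cultures was not excluded by the bound set for it, 0.507 or 0.5 times the smaller pair's effect, since the scramble arrays differed in the list's median by 0.512. Replicate 1 minus replicate 2 was -0.51 for scramble and -0.34 for PRMT5 shRNA, so part of that spread was shared by the pairs, whose effects of -1.09 and -1.01 lay closer together. An effect of PRMT5 on these genes may account for the pattern, as might culture conditions, and 2 pairs cannot separate them. Both PRMT5 shRNA arrays carry the same shRNA name in their titles, so an effect of PRMT5 cannot be told apart from any other effect of that shRNA.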
